A study of Drosophila melanogaster with 2 samples.

How the data were processed

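Chromatin of whole embryos of a transgenic line, sonicated to 200 to 800 bp per the labels, was profiled by ChIP-seq in 2 biological replicates of 1 group. Replicate numbers 2 and 3 were taken from the labels, and no other group or control library was analysed here. Per the labels, 1 free-text field calls each library an input control, while the title, assay, antibody and target fields describe a ChIP library. The submitters' file listing derives each peak list from the library's alignments and a separate control file.

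The authors deposited 4 peak lists in narrowPeak format on assembly dm6: 30000 peaks and background regions for each replicate, 30000 for the pooled replicates, and 2821 peaks kept by the irreproducible discovery rate (IDR) step. Per the file headers and listing, the deposited signal value (column 7) is the peak caller's own enrichment signal for each peak, and it was used here only to rank peaks within a list and to describe them. The deposited −log10 q-value (column 9) was used for ranking in 1 alternative, and it was a constant 3.81 for all IDR peaks. The deposited summit offset (column 10), counted from the peak start, gave summit positions, and column 8 was not used. Aligner, peak caller, IDR threshold and read depth were not given in the sources used here. The 2821 IDR peaks were the 2821 highest of the pooled list by signal value, 16 intervals in the IDR list were repeated with another summit, and 98.0% of IDR peaks (2765) had a summit within 100 bp in each replicate list. The lists held peaks on 2L, 2R, 3L, 3R, 4 and X. Modal peak width was 384 bp in the pooled, IDR and replicate 3 lists and 376 bp in the replicate 2 list. Where peaks are this wide and called from pooled reads, a summit places a site only roughly, and low-ranked entries of a list of fixed length include background.

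Low-ranked peaks, the main background, were the 26661 pooled peaks that overlap no IDR peak (518 that overlap one were left out). They went through the same mapping and calling as the IDR peaks. Genes came from the Ensembl release 115 annotation of BDGP6.54, with transposable elements and pseudogenes left out, and sequence from the RefSeq copy of the same assembly, with no conversion of coordinates. A promoter peak had its summit within 1000 bp of any transcript start site (TSS). Annotation classes took the precedence promoter, 5′ UTR, 3′ UTR, coding exon, noncoding exon, intron, intergenic. Replicate overlap counted summits within 100 bp among the 2821 highest peaks of each list, against 1000 seeded random placements. Shares have 95% Wilson intervals and odds ratios 95% Woolf intervals, or Mantel-Haenszel odds ratios with their intervals where loci of equal gene number were compared. Shares were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment within each family (7 classes, 6 chromosomes, 24 gene lists, 28 consensus sequences, 20 words) at 0.05. GC content used 201 bp around the summit and a permutation test with 100000 resamples. Words of 8 bases within 100 bp of summits, strands merged, were chosen on 2L, 3L and X as the 20 with the smallest Fisher's exact p and then tested on 2R and 3R. Head-to-head pairs had a TSS of another gene on the opposite strand within 500 bp.

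Gene lists, consensus sequences, tests and the alternatives called planned were fixed before the data were examined. The rule for naming genes, fixed at the same time, took the tagged gene, the nearest gene of the 25 highest promoter peaks, up to 4 genes of highest signal per list and the 5 highest peaks over 1000 bp from any TSS. The analyses of AAGCAGT by rank, position, flanking bases and gene list, the element counts at ribosomal protein promoters, the loci of merged tRNA genes and the comparisons other than the promoter share with the 2821 highest low-ranked peaks were added after the data had been seen. AAGCAGT was the first 7-base word on 2L, 3L and X, and its shares by rank are from 2R and 3R. Flanking bases were counted 12 bases to each side, in copies near summits whose 31 bases of context occur once in the genome, and scored by log2 ratios with 1 added to each count.

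Alternatives covered the overlap rule, number of peaks, TSS window, background, window, word length, stricter peak sets and the leaving out of each replicate, in which the 2821 highest peaks of the other replicate's own list replaced the IDR list. The statistics were tested on simulated data. A word put into 5% of 2821 windows was recovered first in 5 of 5 runs, in which 49 of 100 words passed, the planted one and others included, and without a planted word 1 of 100 word tests passed. A list of genes with 40% bound was called in 20 of 20 runs with 2 of 460 calls among the other lists, and 1 of 460 passed when no list differed. Each gene was bound independently in these runs, so they do not cover lists of neighbouring genes that share a peak. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.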

Results

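Binding sites of CG31365, a Drosophila melanogaster protein tagged with GFP at its C terminus, were mapped by ChIP-seq in whole embryos collected over 0 to 24 h of development, males and females together. The series held 1 group of 2 biological replicates, numbered 2 and 3 by the submitters, and each replicate came as a ranked list of 30000 peaks. A list of 30000 peaks called on both replicates together and a list of 2821 peaks that passed the irreproducible discovery rate step (IDR peaks) completed the set. The labels of both libraries described them as ChIP-seq with CG31365 as the target but also called them input controls in 1 free-text field, while the submitters' file listing showed peaks called from these libraries against a separate control file. They were treated here as immunoprecipitated libraries. Read depth was unknown, so intervals cover counting over peaks, genes or words only, and Fisher's exact tests below describe these peak lists, since neighbouring peaks are not independent replicates. All coordinates are on assembly dm6 (BDGP6).

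The same sites led both replicates. The highest IDR peak lay in a coding exon of InR, the insulin-like receptor gene, and the next at a threonine tRNA gene. They held ranks 1 and 2 in each replicate. Of the 2821 highest peaks of replicate 2, 1938 (68.7%, 95% Wilson interval 67.0 to 70.4) had a summit within 100 bp of a summit among the 2821 highest of replicate 3. Random placement on the same chromosomes gave 0.426% on average and 0.815% at most over 1000 placements. The placements were uniform and did not allow for mappability or open chromatin, which can bring peaks of any 2 libraries together. All 100 highest peaks of replicate 2 had a partner anywhere in the list of replicate 3, against 88.5% of ranks 1001 to 3000 and 23.5% of ranks 10001 to 30000. Across the 2711 IDR peaks matched in both lists, which are not independent replicates, the log2 signal values had a Spearman's rho of 0.708 and a Pearson's r of 0.876. The IDR step and the matching both favour peaks on which these replicates agree, so the correlation describes peaks selected in that way.

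**Figure D1:**
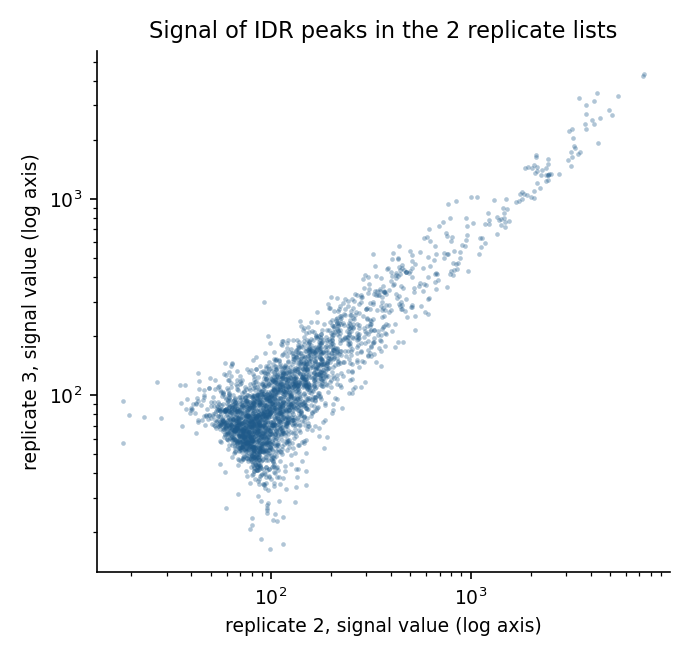
Signal value of each of the 2711 IDR peaks with a summit within 100 bp in both replicate lists, replicate 2 on the horizontal and replicate 3 on the vertical axis (both log axes, 1 point per peak). The points spread widely at low signal and narrow toward the highest peaks (Spearman's rho 0.708).

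The peaks of highest signal lay at genes of varied function. The InR coding-exon peak (3R, 21579750 to 21580828) had a signal value of 11639, 9899 bp from the nearest InR start site, and a further InR peak (3R, 21619178 to 21620127, signal 5092, rank 23) lay 614 bp upstream of a start site. Ilp5, which encodes an insulin-like peptide, had a peak 533 bp upstream (3L, 9824187 to 9824703, signal 4644, rank 27) in an intron of CG43897. T48, needed for apical constriction at gastrulation, had a peak 189 bp upstream in intergenic sequence (3R, 26881260 to 26881881, signal 7280, rank 7). Peaks also lay at dachs, an atypical myosin gene of Fat signalling (2L, 8477775 to 8478646, signal 7019), at Arp2, an actin nucleator subunit gene (X, 16552644 to 16553656, signal 5319), and at mew, an integrin alpha subunit gene (X, 13257015 to 13257559, signal 3753). The peak at tRNA:Thr-AGT-1-4 (3R, 16431475 to 16432108, in an intron of CG31279) reached 11554. The other 24 of the 25 highest promoter peaks included 5 more tRNA genes, tRNA:iMet-CAT-1-5, tRNA:Arg-ACG-1-3, tRNA:Ala-CGC-1-2, tRNA:Ser-GCT-2-5 and tRNA:Lys-TTT-2-1, with signal values from 3743 to 6780. The remainder were at CG14762, CheB93b, CG6465, dpr2, CG10602, toc, CG14990, CG34253, CG8861, Eglp4, Agpat4, CG13088 and disco-r, with signal values from 3625 to 6582. Of the 5 highest peaks over 1000 bp from any start site, InR aside, 1 was intergenic near lncRNA:CR44282 (2R, 24337430 to 24338045, signal 8838) and 1 lay in an intron of bun, a TSC-22 family gene (2L, 12520059 to 12520802, signal 7777). The last 2 lay in an intron of Rtnl1, a reticulon gene (2L, 5000765 to 5001848, signal 7748), and in an annotated 3′ UTR at a position spanned by the Hox gene Antp and CG46458 (3R, 6908005 to 6908816, signal 7722).

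A 7-base word, AAGCAGT, lay under nearly every one of the highest peaks. Among IDR peaks on 2R and 3R it was within 100 bp of 26 of 26 summits of ranks 1 to 50, 19 of 20 of ranks 51 to 100 and 17 of 35 of ranks 101 to 200. The share fell to 14.5% (95% Wilson interval 9.97 to 20.7) for ranks 401 to 800 and 5.75% for ranks 1601 to 2821. Low-ranked peaks, those of the pooled list that overlap no IDR peak, held it in 2.69% of cases (307 of 11400), and 3.28% at ranks 2822 to 5642. The same word led in each replicate's own list: it was at 25 of 25 of the summits of ranks 1 to 50 on 2R and 3R in replicate 2 and at 26 of 27 in replicate 3.

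**Figure D2:**
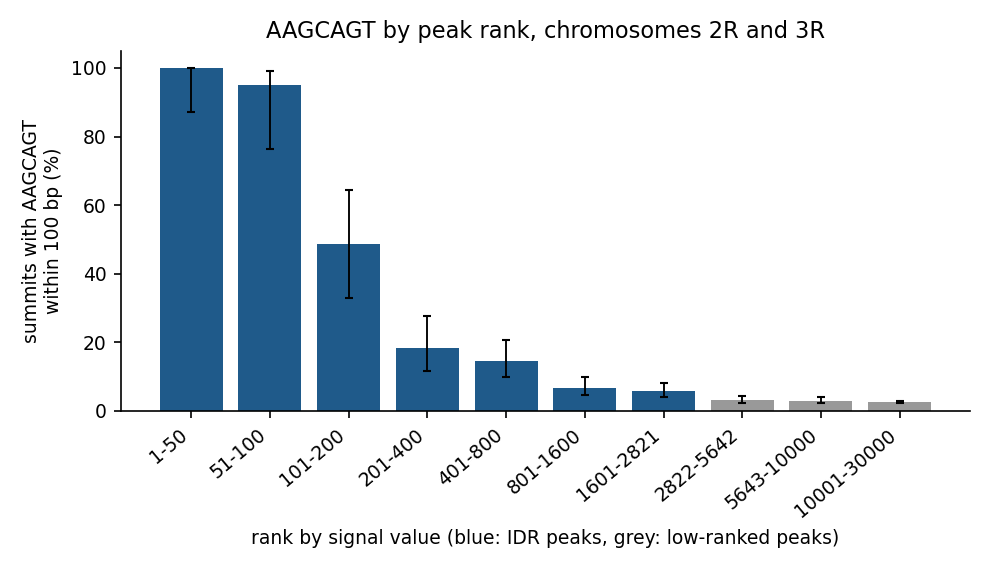
Share of peak summits on 2R and 3R with AAGCAGT on either strand within 100 bp (vertical axis, %), by rank of signal value (horizontal axis; blue bars IDR peaks, grey bars low-ranked peaks). Whiskers are 95% Wilson intervals; the share is 100% for ranks 1 to 50 and 2.53% for ranks 10001 to 30000.

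The word came from a search of all 8-base words, chosen on 2L, 3L and X and tested on 2R and 3R. Of the 20 words chosen, 19 were more frequent at IDR summits than at low-ranked summits on the chromosomes held out, at a Benjamini-Hochberg adjusted p under 0.05 by Fisher's exact test, two-sided. Many of these words overlap in sequence, such as AAGCAGTG and AGCAGTGC, so they are not separate findings. AAGCAGTG led with 8.22% of IDR summits against 0.807% of low-ranked ones (adjusted p = 2.9e-50, Fisher's exact test), followed by ACTGCTTG, the reverse complement of CAAGCAGT, with 7.81% against 0.807% (odds ratio 10.4, adjusted p = 8.9e-47, Fisher's exact test). The word CAGTGTAG did not pass (0.976% against 0.746%, p = 0.387, Fisher's exact test). AAGCAGT led among 7-base words on 2L, 3L and X, and on 2R and 3R it was at 12.8% of IDR summits against 2.69%. The analyses of this word by rank, position and flanking bases were added after the search had been seen. Over all chromosomes 373 of the 2821 IDR peaks (13.2%, interval 12.0 to 14.5) held it.

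AAGCAGT sat at the summits themselves and often more than once. Of 597 copies within 100 bp of IDR summits, 284 (47.6%, interval 43.6 to 51.6) were centred within 20 bp of the summit, where an even spread would put 21.0% and low-ranked peaks had 21.8%. Among the 50 highest peaks 44 held 2 or more copies, with a mean of 2.64 and up to 5, against a mean of 0.0622 copies for ranks 1601 to 2821. At the InR coding-exon peak the copy nearest the summit lay 5 bp from it (3R, 21580284 to 21580290, minus strand) in the sequence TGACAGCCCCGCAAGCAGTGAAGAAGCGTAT, 1 of 4 copies in the window. The tRNA:Thr-AGT-1-4 peak held 2 copies, the nearer 3 bp from the summit (3R, 16431840 to 16431846, minus strand) in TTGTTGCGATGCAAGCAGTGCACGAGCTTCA. At Ilp5 the nearest of 4 copies lay 2 bp from the summit (3L, 9824429 to 9824435, plus strand) in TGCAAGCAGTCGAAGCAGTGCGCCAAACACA, and at dachs there were 5 copies.

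**Figure D3:**
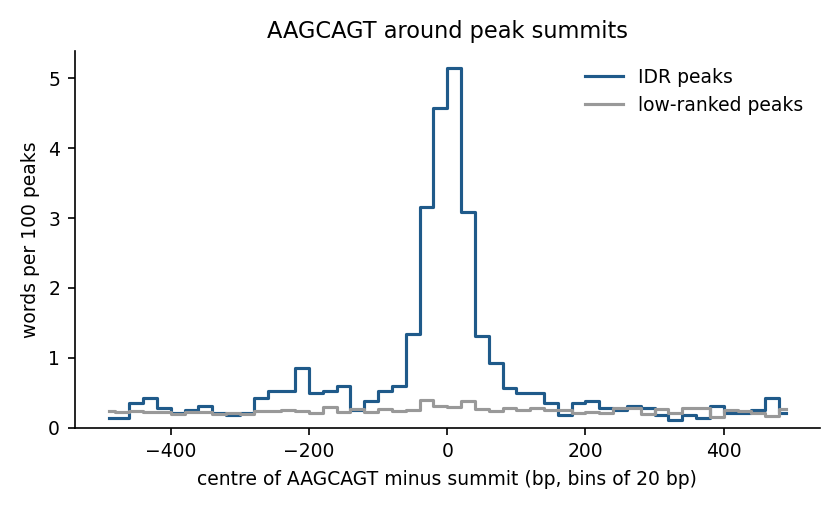
Copies of AAGCAGT per 100 peaks (vertical axis) by the distance of the word's centre from the peak summit in bins of 20 bp (horizontal axis, bp), for the 2821 IDR peaks (blue) and the 26661 low-ranked peaks (grey). The IDR line reaches 5.14 per 100 peaks just right of the summit, where the low-ranked line is at 0.293.

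Bases beside the word differed between bound and other copies. In 306 copies within 50 bp of IDR summits on 2L, 3L, X and 4, the base before the word was C in 55.2% of cases (22.2% in 9076 copies over 1000 bp from any IDR summit) and the base before that was G in 44.8% (22.9%). The base next after the word was G in 49.7%, and the one after that was C in 47.7% (23.8%). Scores built from these flanks ranked the 7605 copies on 2R and 3R, of which 194 (2.55%) lay within 50 bp of an IDR summit. The share was 36.4% (28 of 77, interval 26.5 to 47.5) for the top 1% of scores and 0.684% for the lowest 50%. Copies near start sites lay at IDR summits more often: over all scores it was 5.89% (interval 4.92 to 7.03) for copies within 1000 bp of a start site and 1.42% (1.15 to 1.77) for the others. In the top 1%, with 32 and 45 copies, it was 46.9% and 28.9%, with overlapping intervals (30.9 to 63.6 and 17.7 to 43.4).

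Promoters held most IDR peaks, with or without the word. Summits lay within 1000 bp of an annotated start site in 62.3% of IDR peaks (1758, interval 60.5 to 64.1) against 38.9% of low-ranked peaks (odds ratio 2.60, p = 1.2e-125, Fisher's exact test, two-sided) and 23.7% of random positions. The share was 64.1% for the 373 peaks with AAGCAGT and 62.1% for the 2448 without it. Introns held 25.9% of IDR summits against 37.9% of low-ranked ones, intergenic sequence 9.50% against 17.3% and coding exons 0.425% against 3.03%, and 3′ UTRs were fewer too, each lower at an adjusted p under 0.05 by Fisher's exact test. Set against the 2821 highest of the low-ranked peaks, which hold 59.7% promoter summits, the promoter difference was small (odds ratio 1.12, p = 0.0463, Fisher's exact test) and 0 of the 7 classes differed after adjustment.

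**Figure D4:**
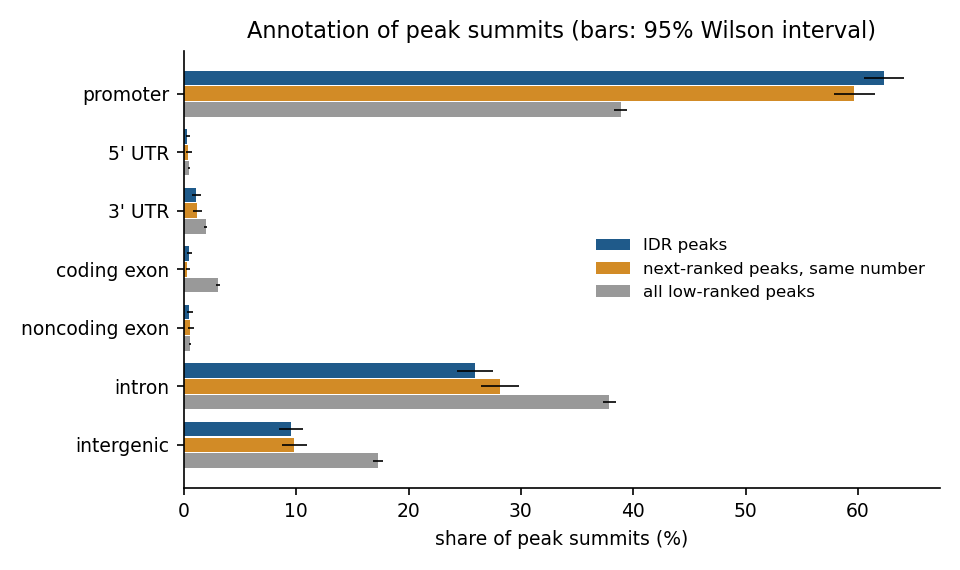
Share of peak summits in each annotation class (horizontal axis, %) for the 2821 IDR peaks (blue), the 2821 highest low-ranked peaks (orange) and all 26661 low-ranked peaks (grey), with 95% Wilson intervals. Promoter summits make up 62.3%, 59.7% and 38.9%.

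Cytoplasmic ribosomal protein genes carried an IDR peak far more often than other genes. Of 86 such genes, 72 (83.7%, lower interval bound 74.5) had an IDR summit within 1000 bp of a start site, against 13.5% of all other protein-coding genes (odds ratio 33.1, adjusted p = 9.2e-47 over 24 lists, Fisher's exact test). The highest were RpS10a (3R, 27651751 to 27652121, signal 1085, 863 bp upstream, in an intron of tau), RpS27 (3R, 25247375 to 25247648, signal 723, in its 5′ UTR), RpL14 (3L, 8600834 to 8601111, signal 659, 18 bp upstream) and RpS4 (3L, 13041681 to 13041951, signal 538, in its 5′ UTR). These 72 peaks ranked from 130 to 2693 with a median of 748, and the median distance to the start site was 23 bp, against 160.5 bp at the 1686 other promoter peaks. Only 2 of the 72 (2.78%, interval 0.765 to 9.57) held AAGCAGT. Other elements stood there: the TCT initiator, the start-site element of ribosomal protein genes, matched in 92.5% of the 67 peaks within 100 bp of a start site, against 16.8% of 590 other IDR peaks at that distance (adjusted p = 3.6e-35, Fisher's exact test), and DRE, the DNA replication-related element, in 28.4% against 8.64% (adjusted p = 2.0e-04, Fisher's exact test). These element counts were made after the result for the gene list had been seen. The TCT initiator belongs to the start sites of this gene list, so its excess was set by the list. Over all IDR summits it was at 21.0% against 21.2% of low-ranked ones. Ribosomal protein promoters without a peak were not compared, so neither element can be tied to the peaks.

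Heat shock genes and tRNA genes were the other 2 lists with more peaks than the rest. Of 21 heat shock genes 10 had an IDR peak (47.6%, interval 28.3 to 67.6, against 13.8% of other genes, adjusted p = 8.6e-04, Fisher's exact test). They included Hsp60A, a mitochondrial chaperonin gene (X, 11108525 to 11109341, signal 2319, in its intron), Hsp83, the fly Hsp90 gene (3L, 3192952 to 3193260, signal 1019, in its 5′ UTR), Hsp27 (3L, 9383763 to 9384035, signal 532, 173 bp upstream) and Hsc70-3 (X, 11807432 to 11807815, signal 182, 507 bp upstream). Heat shock genes were not merged into loci, so any that share a peak were counted each and taken as independent. With only the 1410 IDR peaks of highest signal the share was 14.3% and the call was lost (adjusted p = 0.483, Fisher's exact test). For tRNA genes it was 80 of 290 (27.6%, interval 22.8 to 33.0) against 12.7% of all other genes (odds ratio 2.63, adjusted p = 2.3e-10, Fisher's exact test). The nearest start site of a tRNA gene lay within 1000 bp of 42 IDR summits, 30 of them upstream of it, and 12 of these 42 peaks (28.6%) held AAGCAGT against 13.0% of other IDR peaks (p = 0.0088, Fisher's exact test). Those 12 had a median rank of 47.5 and the other 30 a median rank of 1558.5. Because tRNA genes cluster, genes were also merged into loci when start sites lay within 2000 bp, and 44 of 157 loci with a tRNA gene had a peak against 14.0% of other loci (odds ratio 2.40, 95% interval 1.68 to 3.41). Within loci of equal gene number the odds ratio was 1.75 (1.20 to 2.55).

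**Figure D5:**
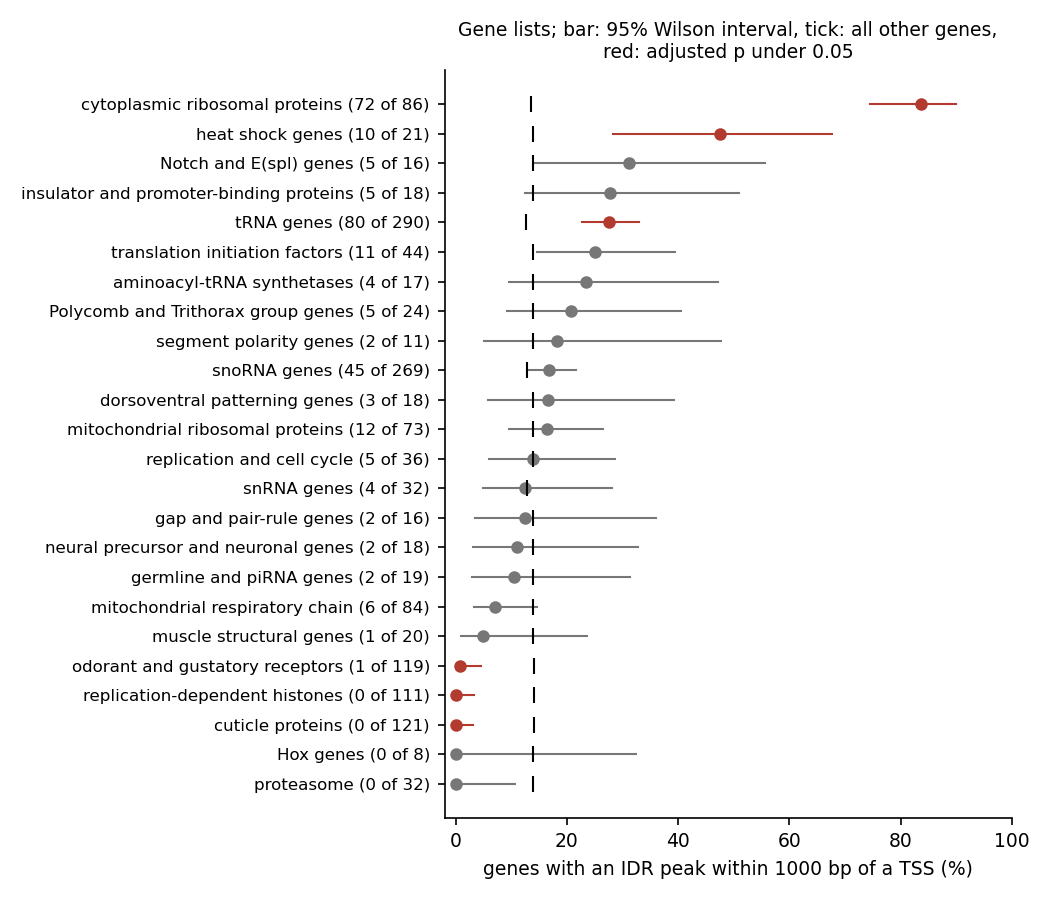
Share of genes with an IDR summit within 1000 bp of a start site (horizontal axis, %) for each of 24 gene lists, with 95% Wilson intervals and a black tick for all other genes. Red marks the 6 lists with an adjusted p under 0.05, from 83.7% of ribosomal protein genes down to 0% of cuticle protein and histone genes.

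Peaks were rare at genes for cuticle, chemosensory receptors and histones. None of 121 cuticle protein genes had an IDR peak at the promoter (0%, upper interval bound 3.08%, adjusted p = 1.5e-07, Fisher's exact test) and 1 of 119 odorant and gustatory receptor genes did (Or88a, 3R, 14108498 to 14108881, signal 211; adjusted p = 3.4e-06, Fisher's exact test). When only genes with any pooled peak at a start site were counted, the receptor list no longer passed (adjusted p = 0.0754, Fisher's exact test). None of 111 replication-dependent histone genes had a peak (adjusted p = 6.1e-07, Fisher's exact test), but these genes stand in near-identical repeats and had no peak in the pooled list of 30000 either, so a lack of binding cannot be told from a lack of uniquely placed reads.

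The other 18 lists did not pass. Of the housekeeping lists, peaks were at 0 of 32 proteasome genes (adjusted p = 0.0600, Fisher's exact test), 11 of 44 translation initiation factor genes (0.138), 12 of 73 mitochondrial ribosomal protein genes (0.747), 6 of 84 respiratory chain genes (0.176), 4 of 17 aminoacyl-tRNA synthetase genes (0.519) and 5 of 36 replication and cell cycle genes (1). Named members with a peak were mRpL13 (signal 5301, a start site shared with CG10602), eIF2Bbeta (2076), eIF6 (904), CysRS (921), ND-ASHI (499) and Mcm2, a replicative helicase subunit gene (432). Developmental lists gave 5 of 16 Notch and E(spl) genes (0.160), among them N (191) and Su(H) (150), and 0 of 8 Hox genes (0.861). In the list of gap and pair-rule genes 2 of 16 had a peak, bcd (251) and cad (178). These 2 are not themselves gap or pair-rule genes, and the other members of that list had none. There were 2 of 11 segment polarity genes (nkd, 170, and ptc, 126) and 3 of 18 dorsoventral genes (ths, 196, tin, 191, and brk, 143). Neural genes gave 2 of 18 (elav, 547, and Syx1A, 163) and muscle genes 1 of 20 (sls, 267). Chromatin regulators gave 5 of 18 insulator and promoter-binding protein genes (0.187), with Chro at 1210, Dref, which encodes the DRE-binding factor, at 420, Cp190 at 416 and Trl, the GAGA factor gene, at 234. There were 5 of 24 Polycomb and Trithorax group genes (0.589), with ph-p at 1481, and 2 of 19 germline genes, vas at 3562 and bgcn at 348. Among RNA genes 45 of 269 snoRNA genes (0.160) and 4 of 32 snRNA genes (1) had a peak. For snoRNA genes the result depended on the window: 2.60% had a summit within 200 bp, fewer than other genes (odds ratio 0.353, adjusted p = 0.0095, Fisher's exact test), and 33.5% within 2000 bp, more than other genes (odds ratio 2.50, adjusted p = 3.1e-10, Fisher's exact test). With the 1410 highest peaks they also passed (odds ratio 2.34, adjusted p = 1.1e-04, Fisher's exact test). The snoRNA genes were not merged into loci, and genes that share a peak were counted each. For example, snoRNA:U49:66Da and snoRNA:U49:66Db were both counted for the RpL14 peak, so these tests take such genes as independent. Initiation factor, proteasome, and Notch and E(spl) genes passed in some alternatives that left out 1 replicate. Of 13945 protein-coding genes 1938 (13.9%) had an IDR peak at the promoter.

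Known promoter and insulator elements were moderately more frequent at IDR summits. Of 28 consensus sequences 9 were more frequent and 2, the Scalloped and SuH sites, less frequent than at low-ranked summits (adjusted p under 0.05, Fisher's exact test). DRE was at 3.01% against 1.26% (odds ratio 2.43, adjusted p = 8.3e-10, Fisher's exact test), the CTCF core at 1.81% against 0.649% (2.82, 5.4e-08), the TATA box at 10.1% against 7.45% (1.39, 1.1e-05) and Motif 7 of core promoters at 5.35% against 3.23% (1.69, 2.3e-07). Against the 2821 highest low-ranked peaks none of the 28 was more frequent after adjustment by Fisher's exact test, and the CA repeat (adjusted p = 0.0248) and the Motif 5 E-box (0.0415) were less frequent, while of 20 words chosen anew against that background 14 passed, led by ACTGCTTG (7.81% against 1.11%, odds ratio 7.54). In that comparison DRE had 3.01% against 2.13% and an unadjusted p of 0.0431 by Fisher's exact test.

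IDR summits were richer in A and T. Median GC content within 100 bp was 39.3% against 43.3% at low-ranked summits, a difference of -3.98 percentage points (p = 1e-05, permutation test, two-sided, the smallest p that 100000 resamples can give), and -1.99 points against the 2821 highest low-ranked peaks. Head-to-head gene pairs were the nearest start site for 20.9% of IDR promoter peaks and 15.2% of low-ranked ones (odds ratio 1.47, p = 5.1e-09, Fisher's exact test), but for 21.5% of promoter summits among the 2821 highest low-ranked peaks (p = 0.707, Fisher's exact test). By chromosome, X held 17.9% of IDR peaks against 16.1% of low-ranked ones (adjusted p = 0.0379, Fisher's exact test), 2R 20.1% against 18.4% (0.0468) and 3L 20.1% against 22.2% (0.0379). Against the 2821 highest low-ranked peaks 0 of 6 chromosomes differed after adjustment, and X had an unadjusted p of 0.0509 by Fisher's exact test.

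The tagged gene itself had no IDR peak. CG31365 (FBgn0051365, 3R, 23123962 to 23126422, minus strand) had 0 IDR summits within 10000 bp. The pooled list had 9 low-ranked peaks there, the highest at rank 7225 with a signal value of 69.1, and the lists of replicates 2 and 3 had 8 and 10. All 9 pooled summits lay outside the gene. In the replicate 3 list a summit of rank 7628 (signal 34.0) lay 56 bp beyond the gene end at 23126422, the 5′ end of this minus-strand gene. The nearest summit in the replicate 2 list was 4555 bp away.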

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

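The tests on peaks with and without AAGCAGT, and those against the 2821 highest low-ranked peaks other than for the promoter share, were chosen only after the results were seen; the other alternatives given here were planned before the data were examined. No paired analysis was possible because the series has 1 group. Ranking by q-value was run for the replicate overlap alone, and read depth was unknown, so no depth limit was set.

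The share of replicate 2 peaks found in replicate 3 (68.7%) was 73.6% with 1 bp of overlap, 63.1% with reciprocal overlap of 50%, 73.3% for summits within 250 bp, 76.5% for 1410 peaks of each list, 61.3% for 5642 peaks of each list and 38.5% for all peaks of both lists. The correlation of signal was 0.763 for the 1410 IDR peaks of highest signal. The promoter share stayed above the background in every alternative run, and lay between 63.3% and 63.6% without either replicate. The count of chromosomes that differed (3) was 1 against chromosome length (chromosome 4), annotated genes or among those 1410 peaks (X in both), and 1 to 2 without either replicate.

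Against the 2821 highest low-ranked peaks 0 annotation classes and 0 chromosomes differed, 0 consensus sequences were more frequent, and the share of head-to-head pairs (20.9%) had an odds ratio of 0.967, on the other side of 1. The cause was not tested, and that background is also smaller and holds more promoters (59.7% against 38.9%). Head-to-head pairs were counted among promoter summits only, so the promoter share of the background does not enter their odds ratio. The count of 9 consensus sequences was 5 in promoter peaks only and 5 in the 1410 highest, and the cause was not tested. Without AAGCAGT peaks the count of 8-base words fell to 11, since the removed peaks held the leading words. With only AAGCAGT peaks 1 gene list (tRNA genes) passed, among 373 peaks, and 6 passed without them. The tagged gene had 9 peaks in the pooled list in place of 0, as that list also holds low-ranked peaks. Heat shock genes (0.483, adjusted p) were lost with the 1410 highest peaks and chemosensory receptors (0.0754) among genes with any pooled peak. The difference in GC content was -1.80 points in the wider window and stayed below 0 elsewhere, and gene lists passing were 7 to 9 without either replicate. The lists that passed only in alternatives were initiation factors (adjusted p 0.0252 without replicate 2 and 0.0447 among genes with any pooled peak), and, without replicate 3, Notch and E(spl) genes (0.0126), proteasome genes (0.0285, fewer peaks) and snoRNA genes (0.00405). The snoRNA list also passed among genes with any pooled peak (0.00326), with the 1410 highest peaks, and in the windows of 200 bp and 2000 bp, in opposite directions.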

Other observations

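The tests below were chosen only after the word and gene list results were seen, and the test against other housekeeping lists also after its own values were seen. In the tRNA tests an extra bound of 1.3 on the lower end of the interval, also within loci of equal gene number, was added after the values were seen and made them stricter. The housekeeping test was later widened to all such lists and made for each list.

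The 2448 IDR peaks without AAGCAGT carried a weaker set of words, some with bases in common with the leading word. Of 20 words chosen on 2L, 3L and X in these peaks, 11 passed on 2R and 3R by Fisher's exact test, led by CACAGTGG (5.13% against 1.32% of low-ranked peaks without the word, odds ratio 4.05, adjusted p = 1.9e-13, Fisher's exact test) and CACTGTGC, the reverse complement of GCACAGTG (4.01% against 1.45%, odds ratio 2.84, adjusted p = 5.5e-07, Fisher's exact test). Both hold CAGTG, the last bases of the leading word AAGCAGTG. Peaks without the word had a median signal value of 180 against 472 with it. The others that passed included words of A and T such as AATATTTA (8.30% against 4.61%, adjusted p = 4.3e-06, Fisher's exact test). GATGGCGC, which does not hold CAGTG, passed too (1.87% against 0.667%, adjusted p = 6.5e-04, Fisher's exact test). Whether any of these words is related to AAGCAGT was not tested. Their background was all low-ranked peaks without AAGCAGT and was not matched for base composition. Over all IDR summits median GC content was 39.3% against 43.3% at low-ranked ones. Whether that difference accounts for the words of A and T was not tested.

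The first pattern weighed is the excess of AAGCAGT at IDR summits. Base composition is argued against by the other 419 words made of its 7 bases, whose median odds ratio on 2R and 3R was 0.971 (highest 2.11) against 5.29 for AAGCAGT, and promoter location by an odds ratio of 5.09 (95% interval 3.65 to 7.09) among summits over 1000 bp from any start site. Counting only copies whose 31 bases of context occur once in the genome left the odds ratio at 5.27 (4.30 to 6.46), against repeated sequence as the cause. Input DNA in place of immunoprecipitated DNA would put copies at summits no more often than further out. On 2R and 3R 46.2% of copies were centred within 20 bp of summits (interval 39.9 to 52.6). An even spread gives 21.0% and low-ranked peaks had 18.0% (14.1 to 22.6), both below that interval, which argues against input DNA. The interval takes in 42.1, the stricter bound set beforehand at 2 times an even spread, so that bound was not met. Over all chromosomes, a count made after the 2R and 3R value was seen and including those on which the word was chosen, the share was 47.6% (43.6 to 51.6). With 1 group no biological explanation was tested.

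The second pattern is the excess of tRNA genes. Chance neighbourhood of AAGCAGT sites cannot be told apart either: counting only peaks without the word the odds ratio was 2.02 (interval 1.51 to 2.70), above the bound set beforehand, but that bound took neighbouring genes that share a peak as separate, and over merged loci of equal gene number the odds ratio without the word was 1.48 (0.988 to 2.21). Sharing of 1 peak by neighbouring tRNA genes cannot be told apart from binding at each: the odds ratio over merged loci was 2.40 (1.68 to 3.41), above the bound of 1.8 set beforehand, but that bound did not allow for merged tRNA loci holding more genes (3.45 on average against 1.68), and the odds ratio was 1.75 (1.20 to 2.55) within loci of equal gene number. Open chromatin and high transcription at tRNA genes were not tested, and no biological explanation was tested.

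The third pattern is the excess of cytoplasmic ribosomal protein genes. AAGCAGT is argued against, since 2.78% of the 72 peaks held it and the odds ratio without such peaks was 35.3. Chromatin open at every housekeeping promoter would put peaks at other housekeeping lists too. IDR peaks did not lie at housekeeping promoters in general. Shares were lower for proteasome (0%), respiratory chain (7.14%) and replication and cell cycle genes (13.9%). They were also lower for mitochondrial ribosomal protein (16.4%) and translation initiation factor genes (25%). The upper bounds of these lists, up to 39.4%, all lie below 41.9%, 0.5 times the 83.7% of the ribosomal protein genes. For aminoacyl-tRNA synthetases (23.5% of 17 genes) the upper bound was 47.3%. The bound of 41.9% was set after these values were seen, and open chromatin was not measured. Whether chromatin more open at ribosomal protein promoters accounts for the excess therefore cannot be told. Signal at very highly transcribed genes, which many ChIP experiments show whatever the target, may account for it and was not tested, since transcript levels were not used here. No biological explanation was tested.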
